A study of Avena sativa with 6 samples.

How the data were processed

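RNA-seq values were used from 6 libraries of peeled oat grains, 3 from ears shaded for 4 days and 3 from unshaded ears. Samples were grouped by the treatment label. Per the labels' protocols, total RNA was extracted with Trizol and fragmented mRNA was copied with random primers into a library prepared with an Illumina kit, and the same text names a PacBio sequencer. The platform is thus not settled by the labels. HISAT2 and StringTie are named in the submitters' processing notes without a version or role. The genome build, annotation, strand setting and the tool behind the authors' test are not given in the sources used here. Genes carry AVESA IDs, or MSTRG IDs for loci outside them, 12944 of 136488 genes.

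The deposited table gives FPKM per gene and library, made by the authors, and the gene length in bases, which was read but not used in a test. It also gives the authors' log2 fold change, which is positive where shaded values are higher, and the authors' p-value and adjusted p-value. The authors' log2 fold change lies below the log2 ratio of the mean FPKM by a median of 0.382 (quartiles 0.373 and 0.390), so the authors' comparison was scaled differently from the FPKM, per the deposited values. In the authors' deposited table the mark up or down goes with an adjusted p under 0.05 and an absolute log2 fold change above 1, with 0 exceptions. FPKM are not counts, so no count model was used. A search over step sizes for whole reads in low values placed, at the best step, 13.0% to 14.3% of values within 0.05 of a whole number. Chance gives 10% at 1 fixed step and more at the best of many. Depth is thus unknown and no interval or floor from counts is given. FPKM also depend on the most abundant genes of a library, since all values share 1 total.

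Genes with a mean of at least 1 FPKM over the 6 libraries (58283, holding 95.96% of the summed FPKM) were tested on log2(FPKM + 1) with a limma linear model (limma 3.58.1, R 4.3.3) with a mean-variance trend in eBayes. Tests were two-sided with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. Folds in FPKM are ratios of group means, and log2 fold changes are on the log2(FPKM + 1) scale. Gene lists were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation and with fry, adjusted over the 34 lists with at least 5 tested genes. With an estimated correlation camera also takes its degrees of freedom from the 6 libraries and not from the genes. A call lost in that setting need not be lost through the correlation. Of 35 lists, the list of seed and oil regulators had 3 tested genes and was not tested. A pathway is counted by camera over 279 KEGG pathways with at least 10 tested genes. Figures and tables were made with Python 3.11 and matplotlib.

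The lists were fixed as text patterns before the data were examined. The text rule set then was not met, since KEGG text reached 40.6% of the tested genes, so lists were matched on KEGG or COG text, which reached 70.4%. The patterns of 21 lists were corrected after gene descriptions had been read, to drop partial-word hits or add the table's wording. Those of the Calvin cycle and light signalling were narrowed after a first result had been seen. The patterns as first written were run as an alternative. Names and functions of genes come from that text, which can join 2 functions at 1 locus.

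Genes are named by a rule set before the data were examined. It took the 10 largest increases and 10 largest decreases among genes past the threshold with wholly separated groups, a mean of at least 5 FPKM and a described function, at most 2 per description. It also took, per list, up to 3 members of the highest mean and up to 2 called members of the largest change with a mean of at least 2 FPKM, named here only for lists described with examples. Lastly it took the most abundant genes for diacylglycerol acyltransferase, oleosin, sucrose synthase, granule-bound starch synthase and 12S globulin, the last matched on seed storage protein text. No gene matched WRI1 in the text used here.

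Alternatives covered the pseudocount, the filter on low values, 4 scalings, the variance model, library weights, the replicate number as a block, a fold threshold, the loss of each library and the average of ear-shaded replicates 1 and 2 as 1 library. The model was tested on simulated data for the comparison of ear-shaded with unshaded libraries over 58283 genes with 200 changed. It recovered 2.7% of genes changed by a log2 fold of 0.5, 46.9% at 1 and 78.7% at 2, with 9 false calls, and made 0 calls where no gene was changed. With 200 genes changed the adjusted threshold is stricter than in the comparison itself, where far more genes passed, so these shares do not carry over to it. No genome was used here, so positions of genes are not given.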

Results

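RNA was measured in peeled grains of BY9, a high-oil oat cultivar, from ears that were covered for 4 days after flowering and from ears left in the light. Each group had 3 libraries, and expression was given as FPKM, fragments per kilobase of gene scaled to the fragments of the library. The number of reads behind each library is unknown, since the values could not be traced back to whole reads. The FPKM of a library summed to between 493004.4 and 561771.7. Unshaded libraries had 50016, 50524 and 54521 genes at 1 FPKM or more, and ear-shaded libraries had 60444, 60606 and 57613. The 50 most abundant genes took 13.82%, 9.72% and 8.93% of all FPKM in the unshaded libraries and 4.24%, 4.23% and 5.1% in the ear-shaded ones. The labels do not say that the 3 libraries of a group came from separate plants, so p-values measure the spread between these libraries, which may be technical. Ear-shaded replicates 1 and 2 were closer to each other (r = 0.9891 over genes, median absolute log2 difference 0.09) than any other pair within a group (r from 0.9495 to 0.965, differences from 0.17 to 0.23). Of their values 0.084% were identical, as in the other pairs within a group (0.065% to 0.093%). Whether they differed by more than sampling noise could not be tested without counts, so they were kept as 2 libraries. With both averaged into 1 library, an alternative chosen after seeing the data, 31064 genes passed in place of 37227, 20590 of them higher, and 22 gene lists passed as before.

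The comparison of shaded with unshaded ears asks what light on the ear contributes to grain filling and oil. Most photosynthesis genes were higher in grains of shaded ears (145 of 167 light-reaction genes), and most storage protein genes were lower (72 of 90). Lists for oil bodies (20 lower and 10 higher of 33), fatty acid synthesis (40 and 10 of 73) and starch synthesis (31 and 16 of 61) were lower on balance. These list calls hold at a preset correlation between genes, and each was lost with an estimated correlation (adjusted p from 0.518 to 0.696). The estimates were 0.286 for light reactions, 0.593 for storage proteins, 0.123 for fatty acid synthesis and 0.178 for starch synthesis. All lie above the preset 0.01, so p-values at the preset may be too small. For oil bodies the estimated correlation was -0.0125, below the preset 0.01, so that loss did not come from a higher correlation. The setting with an estimate also takes fewer degrees of freedom, which raises p whatever the correlation is. On the log2(FPKM + 1) scale, with at most 2 genes taken per description, the largest increases among genes of at least 5 FPKM were in class 3 lipases, linoleate 9S-lipoxygenases, photosystem I subunits and the plastid glyceraldehyde-3-phosphate dehydrogenase of carbon fixation. The largest decreases by the same rule were in serpins, gliadin-domain storage proteins, an endochitinase and oleosins. Of 58283 genes tested with limma, 37227 (63.9%) passed an adjusted p of 0.05, 24724 of them higher and 12503 lower under shading. Of these, 9475 were higher and 6088 lower by at least 2-fold on the log2(FPKM + 1) scale, which understates the change of low genes. The 3 libraries of one group lay wholly above those of the other in 70.2% of the tested genes, where chance gives 10%. The first principal component, 86.1% of the variance, separated the groups, with unshaded replicate 3 (-100.84) and ear-shaded replicate 3 (95.49) nearest to the other group.

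The split of the calls into higher and lower depended on how libraries were scaled. With the FPKM as deposited 66.4% of the calls were higher under shading, and the median log2 fold change of all tested genes was 0.26. Median-of-ratios scaling gave 16333 higher and 18139 lower genes, 47.4% higher, and moved that median to -0.02. Quantile normalization gave 53.2% higher with a median of 0.05, and scaling each library to the same sum gave 71.6% with a median of 0.41. Changes of gene lists are therefore given below as the list's median log2 fold change minus that of all tested genes. The authors' deposited table marks 18232 genes as up and 17674 as down. Of its marked genes among those tested, 9786 up and 10852 down were called in the same direction with limma and 0 in the opposite one. A further 14938 limma calls higher and 1651 lower carry no mark there. The marks need an absolute log2 fold change above 1 and rest on another scaling.

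Photosynthesis genes made up the most strongly raised lists. Of 167 genes of the light reactions and the light-harvesting antenna, 145 were higher under shading, 8 were lower and 14 did not pass. Adjusted over the list alone, 146 were higher and 8 lower. Their summed expression was 291 ± 27.3 FPKM (SD, n = 3) in unshaded and 3020 ± 326 FPKM in ear-shaded grains, a 10.4-fold difference. The list's median lay 2.38 above that of all genes (camera, adjusted p = 1.84e-22), a call lost with an estimated correlation between genes (adjusted p = 0.696 with an estimated correlation). The photosystem I subunit psaL (AVESA.00010b.r2.4DG0780370) was at 1.14 ± 0.516 FPKM in unshaded and 113 ± 16.3 FPKM in ear-shaded grains. A further psaL copy (AVESA.00010b.r2.4DG0793320) was at 0.841 ± 0.358 and 72.9 ± 7.87 FPKM. The antenna protein LHCB1 (AVESA.00010b.r2.5CG0875470) went from 0.606 ± 0.280 to 69.1 ± 11.5 FPKM, a log2 fold change of 5.45 (SE 0.18, limma adjusted p = 5.02e-06). Plastocyanin (AVESA.00010b.r2.7AG1198570) rose 44.5-fold and the oxygen-evolving protein psbO (AVESA.00010b.r2.2CG0289220) 48.5-fold in mean FPKM.

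The Calvin cycle list, the enzymes of carbon fixation, had 41 of 45 genes higher and 0 lower, adjusted over the list alone as well. Its summed expression was 32.5 ± 9.28 FPKM in unshaded and 1070 ± 172 FPKM in ear-shaded grains. Its median lay 3.33 above that of all genes (camera, adjusted p = 5.86e-16; adjusted p = 0.696 with an estimated correlation). The list was narrowed to the plastid form of glyceraldehyde-3-phosphate dehydrogenase after a first result had been seen, so its counts are not independent of the pattern. As first written it had 35 of 43 genes higher and 1 lower, with a relative median of 3.01. The wider KEGG pathway of carbon fixation in photosynthetic organisms had 112 of 206 genes higher and 34 lower, with a relative median of 0.32 (camera, adjusted p = 0.0178; adjusted p = 0.985 with an estimated correlation). Named copies of the plastid glyceraldehyde-3-phosphate dehydrogenase subunit GAPA led the list. AVESA.00010b.r2.2AG0224760, AVESA.00010b.r2.2CG0304140 and AVESA.00010b.r2.2DG0378630 were at 0.794 ± 0.128, 0.827 ± 0.242 and 0.782 ± 0.187 FPKM in unshaded grains. In ear-shaded grains they were at 93.3 ± 23.6, 88.1 ± 20.2 and 72.6 ± 14.4 FPKM. Of 60 genes of tetrapyrrole and chlorophyll synthesis, 51 were higher and 3 lower, adjusted over the list alone as well, and the median lay 0.87 above that of all genes (camera, adjusted p = 8.83e-09; adjusted p = 0.696 with an estimated correlation). Protochlorophyllide reductase (AVESA.00010b.r2.6AG1073010), the step of chlorophyll synthesis that needs light in flowering plants, was at 0.0791 ± 0.0688 FPKM in unshaded and 31.5 ± 4.57 FPKM in ear-shaded grains, 398-fold and, without unshaded replicate 3, 744-fold higher. Magnesium-protoporphyrin monomethyl ester cyclase rose in 3 named copies, to 41.5 ± 9.14 (AVESA.00010b.r2.3AG0427210), 33.0 ± 4.87 (AVESA.00010b.r2.3DG0528470) and 35.2 ± 8.05 FPKM (AVESA.00010b.r2.UnG1500030). Porphobilinogen synthase (AVESA.00010b.r2.6CG1139600) rose 1.45-fold, a call that ended with median-of-ratios scaling.

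**Figure D1:**
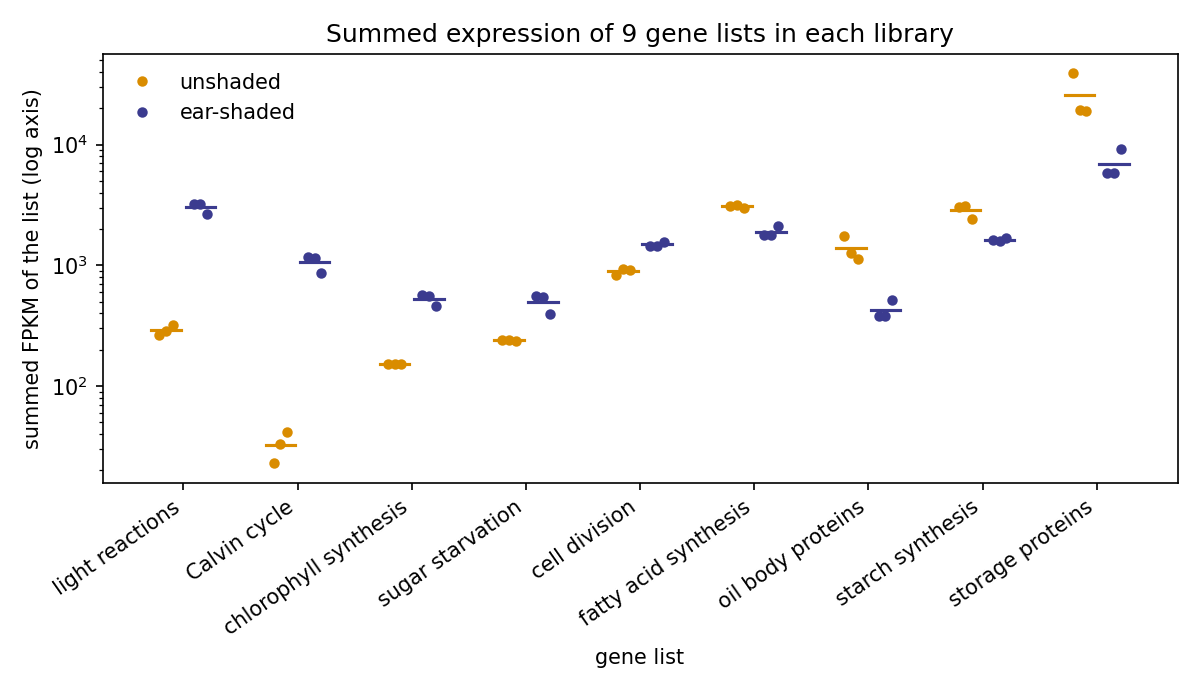
Summed FPKM of 9 gene lists, on a log axis, in each of the 3 unshaded (orange) and 3 ear-shaded (blue) libraries, with short lines at the group means. The light-reaction list lies between 265 and 320 FPKM in unshaded and between 2650 and 3230 FPKM in ear-shaded libraries, and the storage protein list between 19000 and 38900 and between 5840 and 9250 FPKM.

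Storage protein genes were lower. None of the 90 genes tested was higher, 72 were lower and 18 did not pass. Adjusted over the list alone, 74 were lower. The summed expression was 25700 ± 11400 FPKM in unshaded and 6980 ± 1960 FPKM in ear-shaded grains, 3.69-fold lower. The list's median lay at -2.12 relative to all genes (camera, adjusted p = 3.3e-18; adjusted p = 0.696 with an estimated correlation). The most abundant gene with a gliadin domain (AVESA.00010b.r2.1DG0150510) was at 2510 ± 1200 and 495 ± 197 FPKM, a log2 fold change of -2.31 (SE 0.44, limma adjusted p = 0.0025). A further abundant copy (AVESA.00010b.r2.3DG0571355) was at 1290 ± 496 and 342 ± 109 FPKM. For AVESA.00010b.r2.3DG0571360, at 1270 ± 494 and 530 ± 278 FPKM, the call ended without unshaded replicate 1 or 2 or ear-shaded replicate 1 or 2 and without the filter, and the sign turned with quantile normalization. The copies AVESA.00010b.r2.4AG0586600 and AVESA.00010b.r2.4DG0731050 fell 26.3-fold and 15.5-fold in mean FPKM, and a gene with seed storage protein text (AVESA.00010b.r2.UnG1478840) fell 14.6-fold. For AVESA.00010b.r2.4DG0731050 the fold was 9.90 without unshaded replicate 1 and 32.9 without ear-shaded replicate 3. The most abundant gene with such text (AVESA.00010b.r2.UnG1428550) was at 788 ± 514 and 223 ± 76.2 FPKM, 3.54-fold lower and 2.21-fold without unshaded replicate 1, a call that ended with quantile normalization. Members of these families are close copies in a hexaploid genome, so reads may be divided among them and single genes are less certain than the sum.

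Other genes were lower by as much. The protease inhibitors of the serpin family (AVESA.00010b.r2.4AG0596420 and AVESA.00010b.r2.4DG0740430) fell from 94.8 ± 45.8 to 3.03 ± 1.79 FPKM and from 146 ± 86.6 to 6.13 ± 2.69 FPKM. These are folds of 31.2, or 47.1 without ear-shaded replicate 3, and of 23.8, or 15.9 without unshaded replicate 1. An endochitinase (AVESA.00010b.r2.6AG1043730) fell from 3810 ± 1270 to 219 ± 92.9 FPKM, a log2 fold change of -4.14 (SE 0.40, limma adjusted p = 0.000112). The SEC61 alpha subunit (AVESA.00010b.r2.UnG1444170), part of the channel through which proteins enter the endoplasmic reticulum, fell from 36.3 ± 4.23 to 1.09 ± 0.911 FPKM, 33.3-fold and, without ear-shaded replicate 3, 63.7-fold. A gene with immunoglobulin binding text (AVESA.00010b.r2.7CG0656555) fell from 475 ± 199 to 26.0 ± 6.95 FPKM.

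The genes of oil synthesis did not all move together. Of 73 genes of plastid fatty acid synthesis, 40 were lower and 10 higher, adjusted over the list alone as well, and the median lay at -0.74 relative to all genes (camera, adjusted p = 9.11e-07; adjusted p = 0.696 with an estimated correlation). Their summed expression was 3090 ± 80.4 FPKM in unshaded and 1890 ± 191 FPKM in ear-shaded grains. Stearoyl-ACP desaturase, which makes oleate, was lower in 3 of 4 named copies: AVESA.00010b.r2.4DG0783700 fell from 196 ± 18.1 to 81.4 ± 14.1 FPKM, AVESA.00010b.r2.3CG0514650 from 82.5 ± 9.44 to 18.6 ± 4.20 FPKM and AVESA.00010b.r2.4AG0640590 from 47.6 ± 5.67 to 11.9 ± 2.30 FPKM. The fourth copy (AVESA.00010b.r2.4DG0771800) was at 163 ± 18.7 and 130 ± 23.0 FPKM and did not pass. It passed as lower with median-of-ratios scaling (log2 fold change -0.72), with library weights (-0.45) and without ear-shaded replicate 3 (-0.47), and it turned to a positive sign with quantile normalization. The thioesterase FATA (AVESA.00010b.r2.5CG0880950), which releases finished fatty acids, fell from 178 ± 15.5 to 76.2 ± 4.77 FPKM.

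The 33 genes of oil body proteins had 20 lower and 10 higher, and adjusted over the list alone 20 lower and 11 higher. The median lay at -1.01 relative to all genes (camera, adjusted p = 0.00135; adjusted p = 0.518 with an estimated correlation), a call that ended with KEGG text alone. Genes with the text of oleosins, the coat proteins of oil bodies, fell 23.0-fold (AVESA.00010b.r2.4AG0601950) and 18.1-fold (AVESA.00010b.r2.4DG0745830) in mean FPKM. The most abundant oleosin (AVESA.00010b.r2.2CG0312110) fell from 128 ± 17.1 to 24.1 ± 7.51 FPKM. The caleosin-type peroxygenases AVESA.00010b.r2.2CG0309000, AVESA.00010b.r2.2DG0373740 and AVESA.00010b.r2.2AG0229850 fell 4.58-fold, 5.52-fold and 3.99-fold. In the list of triacylglycerol assembly, 14 of 65 genes were higher and 21 lower, the median was 0.09 and the median relative to all genes -0.17, and the camera test missed the threshold (adjusted p = 0.0646). It passed downward with median-of-ratios scaling, where 7 genes were higher and 28 lower, with quantile normalization and without unshaded replicate 2, while scaling each library to the same sum gave 20 higher and 18 lower. The acyltransferase DGAT1 (AVESA.00010b.r2.1AG0074620), the last step of oil assembly, fell from 15.3 ± 2.04 to 2.62 ± 0.155 FPKM. The most abundant gene with diacylglycerol acyltransferase text (AVESA.00010b.r2.6CG1086680) was at 17.3 ± 0.584 and 12.3 ± 1.01 FPKM, a call that ended without ear-shaded replicate 2. A lysophospholipid acyltransferase (AVESA.00010b.r2.1AG0011680) rose 7.51-fold and a lysophosphatidic acid acyltransferase (AVESA.00010b.r2.5AG0822060) fell 1.81-fold. The glycerol-3-phosphate acyltransferases AVESA.00010b.r2.3CG0512060 and AVESA.00010b.r2.4DG0765710 had 41.9 ± 27.3 and 32.1 ± 19.1 FPKM in unshaded grains. In ear-shaded grains they had 69.5 ± 18.3 and 44.5 ± 9.77 FPKM, and neither passed. Without unshaded replicate 3 both passed as higher, with log2 fold changes of 1.39 and 1.06, the first also with library weights.

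Lipid-cleaving and lipid-oxidising enzymes were among the largest increases on the log2(FPKM + 1) scale. The class 3 lipases AVESA.00010b.r2.7AG1196350 and AVESA.00010b.r2.1DG0140510 rose from 1.73 ± 1.30 to 226 ± 110 FPKM and from 2.38 ± 1.42 to 273 ± 135 FPKM. The linoleate 9S-lipoxygenases AVESA.00010b.r2.7CG0697730 and AVESA.00010b.r2.4AG0602020 rose from 3.50 ± 1.27 to 259 ± 117 FPKM and from 2.71 ± 1.03 to 204 ± 99.8 FPKM. In mean FPKM the lipases rose 131-fold and 115-fold and the lipoxygenases 74.1-fold and 75.3-fold, the first lipase 231-fold without unshaded replicate 2. Protochlorophyllide reductase AVESA.00010b.r2.6AG1073010 (398-fold), the GAPA copies AVESA.00010b.r2.2AG0224760 (117-fold) and AVESA.00010b.r2.2CG0304140 (107-fold) and LHCB1 AVESA.00010b.r2.5CG0875470 (114-fold) thus rose by more than the lipoxygenases in mean FPKM. Without unshaded replicate 3 the fold of AVESA.00010b.r2.6AG1073010 was 744. A non-specific lipid-transfer protein (AVESA.00010b.r2.7CG0683350) rose from 0.828 ± 0.616 to 84.0 ± 43.2 FPKM, a log2 fold change of 5.42 (SE 0.45, limma adjusted p = 6.79e-05), 101-fold in mean FPKM and 165-fold without unshaded replicate 2. The list of lipid breakdown by lipases, beta-oxidation and the glyoxylate cycle had 35 of 54 genes higher and 3 lower, and adjusted over the list alone 35 and 4 (camera, adjusted p = 0.00954; adjusted p = 0.696 with an estimated correlation). The call ended with the patterns as first written and with COG text alone. The class 3 lipases and lipoxygenases above are not among the list's members. Its most abundant members, an acyl-CoA oxidase (1.22-fold) and an acetyl-CoA acyltransferase (1.23-fold), did not pass. A further acyl-CoA oxidase, next in abundance, rose 1.60-fold, a call that ended with median-of-ratios scaling. The called members of the largest change with a mean of at least 2 FPKM were 2 other acyl-CoA oxidases. These rose 5.81-fold and 8.58-fold in mean FPKM (limma, adjusted p = 0.000219 and 0.000427), and both calls held with median-of-ratios scaling. The KEGG pathway of fatty acid degradation did not pass (relative median 0.10, camera, adjusted p = 0.486).

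Starch synthesis genes were lower, with 31 of 61 lower and 16 higher, and adjusted over the list alone 34 lower and 17 higher. The median lay at -0.64 relative to all genes (camera, adjusted p = 0.000661; adjusted p = 0.696 with an estimated correlation), and the summed expression fell from 2850 ± 385 to 1620 ± 45.7 FPKM. The list's call ended with COG text alone. An ADP-glucose pyrophosphorylase (AVESA.00010b.r2.UnG1437920), the committed step of starch synthesis, fell from 146 ± 33.6 to 22.6 ± 1.70 FPKM. A starch synthase (AVESA.00010b.r2.7AG1239790) fell from 21.0 ± 2.90 to 4.02 ± 0.354 FPKM and a branching enzyme (AVESA.00010b.r2.6AG1020500) from 211 ± 32.7 to 78.8 ± 10.2 FPKM. Granule-bound starch synthase, which makes amylose, was 1.58-fold lower for AVESA.00010b.r2.5CG0866950 (176 ± 22.1 FPKM in ear-shaded grains) and 1.44-fold lower for AVESA.00010b.r2.7AG1201490 (131 ± 13.1 FPKM). Both of these calls ended without unshaded replicate 1 or 2 or ear-shaded replicate 1 or 2 and without the filter, and both turned to a positive sign with quantile normalization. The second also lost its call when each library was scaled to the same sum. Of 41 starch breakdown genes, 12 were higher and 8 lower, adjusted over the list alone 12 and 6, and the list did not pass (camera, adjusted p = 0.741). With median-of-ratios scaling and with quantile normalization 11 were higher and 16 lower. Beta-amylases led its increases: AVESA.00010b.r2.2CG0274370 rose from 7.97 ± 5.62 to 192 ± 90.4 FPKM (24.2-fold, and 40.5-fold without unshaded replicate 2), AVESA.00010b.r2.1AG0057720 from 2.58 ± 0.499 to 28.9 ± 3.33 FPKM and AVESA.00010b.r2.2DG0351390 from 5.39 ± 1.02 to 26.0 ± 12.2 FPKM.

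The list of sucrose cleavage and sugar transport had 54 of 108 genes higher and 22 lower, and adjusted over the list alone 56 and 22. It did not pass (median 0.19 relative to all genes, camera, adjusted p = 0.297), and its summed expression was 3840 ± 290 FPKM in unshaded and 2920 ± 226 FPKM in ear-shaded grains. The most abundant members were sucrose synthases, which cleave imported sucrose. AVESA.00010b.r2.4CG1266890 fell from 575 ± 60.1 to 228 ± 31.6 FPKM and AVESA.00010b.r2.5AG0811470 from 337 ± 60.7 to 170 ± 16.0 FPKM, the latter call lost with quantile normalization. AVESA.00010b.r2.6AG1056840 was at 667 ± 73.9 and 416 ± 62.9 FPKM, a call that ended without any one of unshaded replicates 1, 2 and 3 or ear-shaded replicates 1 and 2 and without the filter, and that turned to a log2 fold change of 0.47 with quantile normalization. An invertase (AVESA.00010b.r2.2AG0245070) rose 6.31-fold, from 2.88 ± 2.39 to 18.2 ± 5.85 FPKM. Its unshaded replicates were at 1.20, 5.62 and 1.82 FPKM, and replicate 2 lowers the fold: the unshaded mean was 0.158 of the shaded one with that library and 0.0831 of it without, where the log2 fold change was 2.89 in place of 2.42. A SWEET sugar transporter that shares its locus text with a bile acid symporter family (AVESA.00010b.r2.6AG1045920) rose 10.5-fold.

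The list of sugar starvation and dark response had 32 of 54 genes higher and 7 lower, adjusted over the list alone as well, and its median lay 0.38 above that of all genes (camera, adjusted p = 0.0221; adjusted p = 0.696 with an estimated correlation). The call ended without unshaded replicate 3 (0.34), with genes of a mean of at least 5 FPKM and with COG text alone. Proline dehydrogenase, the first step of proline breakdown, led it: AVESA.00010b.r2.1AG0059200 rose from 6.04 ± 0.631 to 70.9 ± 22.9 FPKM. The copies AVESA.00010b.r2.1DG0177680, AVESA.00010b.r2.1CG0085600 and AVESA.00010b.r2.1DG0177690 rose 7.64-fold, 8.20-fold and 49.2-fold. An asparagine synthetase (AVESA.00010b.r2.4CG1322550), of a family known as lowered by light, rose from 0.852 ± 0.863 to 21.6 ± 2.22 FPKM, 25.4-fold and, without unshaded replicate 2, 61.2-fold. The family as a whole did not rise: 7 of 12 genes were higher and 3 lower. Its sum was 91.9 ± 7.07 FPKM in unshaded and 93.7 ± 3.64 FPKM in ear-shaded grains.

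Genes of cell division and DNA replication were also higher, 102 of 171 against 13 lower, and adjusted over the list alone 103 and 13. The median lay 0.20 above that of all genes (camera, adjusted p = 0.00241; adjusted p = 0.696 with an estimated correlation). With median-of-ratios scaling 53 were higher and 21 lower, and the call ended with COG text alone. The KEGG pathways of DNA replication (96 higher and 31 lower of 203) and cell cycle (140 and 33 of 314) did not pass. Their relative medians were 0.02 and 0.07 (camera, adjusted p = 0.461 and 0.199). The replication helicase subunit MCM4 (AVESA.00010b.r2.UnG1439890) rose from 0.450 ± 0.109 to 9.24 ± 0.185 FPKM. The replication clamp PCNA was at 32.8 ± 3.11 and 55.8 ± 11.4 FPKM for AVESA.00010b.r2.6AG1047070, a call that ended with median-of-ratios scaling. For AVESA.00010b.r2.6DG1153980 the means differed 1.12-fold, did not pass, and turned to a negative sign with that scaling. Genes whose text joins a DNA polymerase delta subunit with an unrelated ubiquitin ligase rose 2.83-fold (AVESA.00010b.r2.2CG0301790) and 13.6-fold (AVESA.00010b.r2.6DG1160380), so which of the 2 functions they carry is not settled.

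Marker lists of other tissues that a peeled grain could hold were tested as well. The surface-layer list of cuticle and wax genes had 54 of 96 genes higher and 9 lower, adjusted over the list alone as well, with a median 0.61 above that of all genes (camera, adjusted p = 0.0177; adjusted p = 0.696 with an estimated correlation). The call ended without the filter on low values, where the relative median was 0.03, and without unshaded replicate 2 (0.39). The KEGG pathway of cutin, suberine and wax biosynthesis had 27 of 55 genes higher and 8 lower. It did not pass (relative median 0.31, camera, adjusted p = 0.585). The surface-layer list's summed expression was 2710 ± 1580 FPKM in unshaded and 4540 ± 334 FPKM in ear-shaded grains, and the libraries overlapped, with unshaded replicate 3 at 4490 FPKM. Its 3 most abundant members, with lipid-transfer protein text, did not pass. They were at 633 ± 404 and 639 ± 104 FPKM (AVESA.00010b.r2.3CG0506070), 411 ± 285 and 637 ± 98.4 FPKM (AVESA.00010b.r2.3DG0552410) and 421 ± 263 and 231 ± 58.2 FPKM (AVESA.00010b.r2.7CG0683340). The first turned sign with median-of-ratios scaling and without unshaded replicate 2 and passed as higher with quantile normalization. The second passed as higher with quantile normalization, library weights and without unshaded replicate 3 (log2 fold change 1.40). The third passed as lower with library weights and without unshaded replicate 2 (-1.14), and turned sign with quantile normalization. Other members with the same text rose, AVESA.00010b.r2.UnG1418490 from 3.41 ± 1.70 to 174 ± 77.3 FPKM and AVESA.00010b.r2.7CG0683350 by 101-fold, or 165-fold without unshaded replicate 2. The pollen and anther list had 24 of 42 higher and 3 lower, adjusted over the list alone 26 and 3 (camera, adjusted p = 0.0292; adjusted p = 0.696 with an estimated correlation). Its most abundant member carries Ole e I domain text, which is not limited to pollen. The embryo and late maturation list had 54 of 87 higher and 16 lower, adjusted over the list alone 56 and 16, and missed the threshold (camera, adjusted p = 0.0533), with a median 0.66 above that of all genes. It passed upward with median-of-ratios scaling (adjusted p = 0.00579), quantile normalization (0.00978), a mean of at least 5 FPKM (8.26e-05) and library weights (0.0281). It also passed without unshaded replicate 1 (relative median 0.59) or 3 (0.83), and its highest adjusted p, without the filter, was 0.899. Its summed expression was 652 ± 186 FPKM in unshaded and 1450 ± 139 FPKM in ear-shaded grains. In all, 22 of 34 gene lists passed camera, 17 upward and 5 downward, and 0 passed with an estimated correlation, with 0.518 the lowest adjusted p for the oil body list. All 22 also passed fry, which does not compare a list with other genes.

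**Figure D2:**
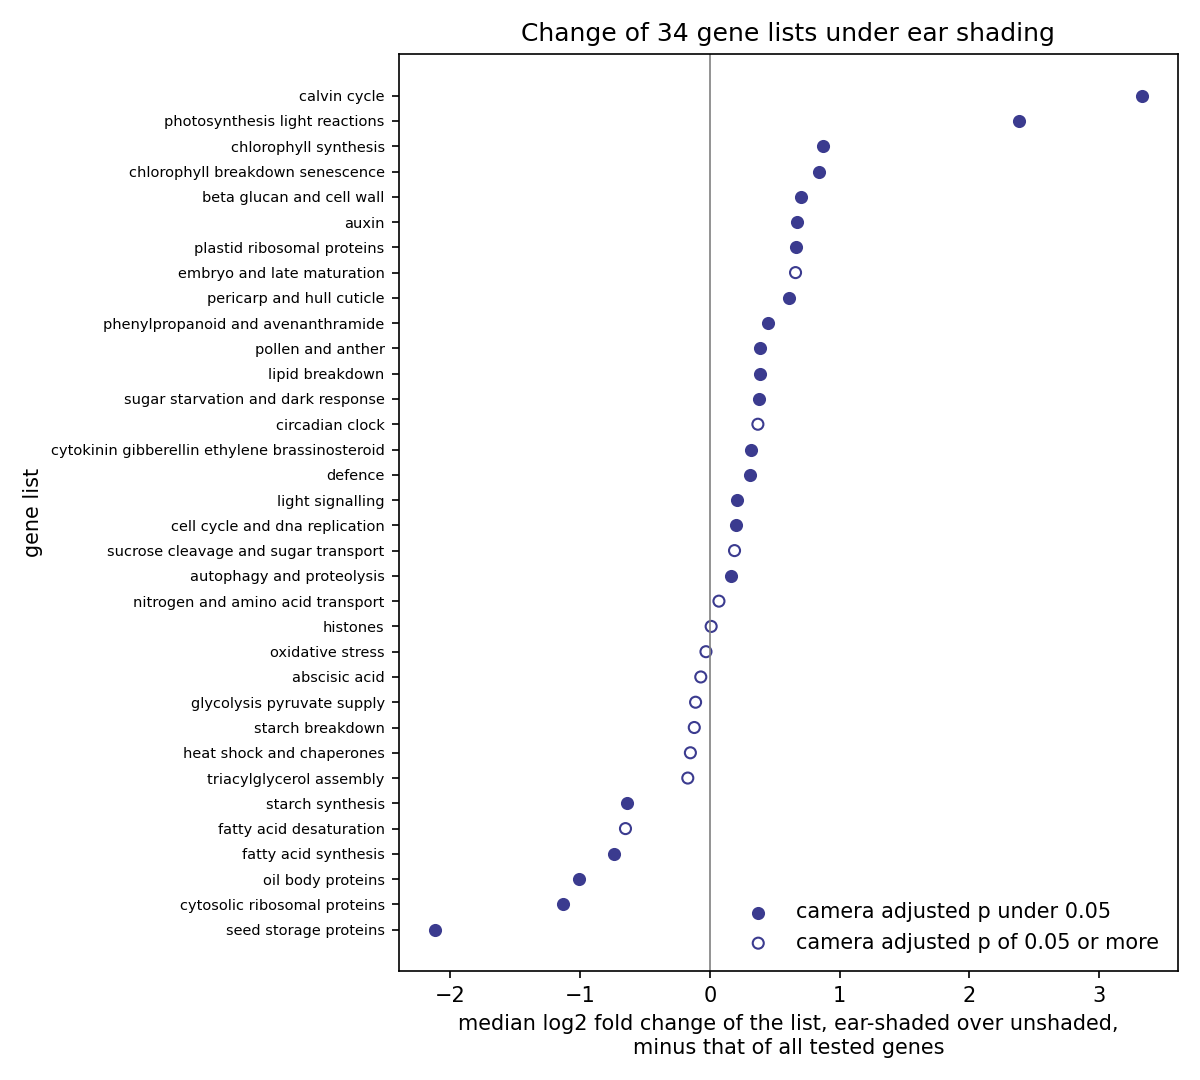
Median log2 fold change of each of 34 gene lists, ear-shaded over unshaded, minus the median of all tested genes, with 1 point per list. Filled points are lists with a camera adjusted p under 0.05 at the preset correlation of 0.01, and the medians run from -2.12 for storage proteins to 3.33 for the Calvin cycle.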

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

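The alternatives on KEGG text alone, COG text alone, patterns as first written, AVESA loci alone, the loss of both unshaded replicate 3 and ear-shaded replicate 3 and the average of ear-shaded replicates 1 and 2 were chosen after seeing the data. The cause of a change was not tested unless stated.

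Of the counts, 37227 changed genes became 56196 without a filter (38730 higher), where more genes were tested, and 12567 with a mean of at least 5 FPKM (7292 higher and 5275 lower), where fewer were. An absolute log2 fold change of at least 1 left 15563, 9475 higher and 6088 lower. Median-of-ratios scaling gave 16333 higher genes. Loss of each library gave 30665 to 38069 changed genes, 20290 to 25940 higher and 10375 to 12603 lower. Without both replicates 3, 40127 were changed, 27134 of them higher. With ear-shaded replicates 1 and 2 averaged, 31064 were changed. Of the 37227 calls, 28836 were kept in direction with median-of-ratios scaling, 30710 with quantile normalization and 35631 with each library scaled to the same sum.

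With an estimated correlation 0 of the 22 lists passed camera, and oil bodies were lost although their estimate (-0.0125) lay below the preset 0.01. Since that setting also takes fewer degrees of freedom, it cannot show that correlation ended a call. The relative medians, which that setting leaves as they are, were -0.74 for fatty acid synthesis, -1.01 for oil bodies, 2.38 for light reactions, -0.64 for starch synthesis, -2.12 for storage proteins, 0.38 for sugar starvation and 0.20 for cell division. Triacylglycerol assembly passed with median-of-ratios scaling (-0.19), quantile normalization (-0.16) and AVESA loci alone (-0.17), and ranged from -0.24 to -0.12 without each library, passing without unshaded replicate 2. Sugar starvation missed with a mean of at least 5 FPKM (0.35) and COG text alone (-0.04), and ranged from 0.33 to 0.43 without each library, missing without unshaded replicate 3 (0.34). Sugar transport passed with fry (0.19), and so did starch breakdown, glycolysis, embryo and late maturation, clock, oxidative stress, abscisic acid and nitrogen transport, 8 of the 12 lists that missed camera. Fry does not compare a list with other genes, and for starch breakdown, glycolysis and abscisic acid its direction was up where that of camera was down. Sugar transport turned to -0.19 with COG text alone. KEGG text alone ended the oil body call (-0.13), and COG text alone those of starch synthesis (-0.59) and cell division (0.24), with fewer members in each list.

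Of 1952 values for 93 named genes, 1870 kept their direction and side of the threshold, 44 lost the threshold, 22 gained it and 16 turned, and 72 genes kept both under all planned settings. With quantile normalization AVESA.00010b.r2.4DG0771800 turned to 0.24, AVESA.00010b.r2.5CG0866950 to 0.07, AVESA.00010b.r2.7AG1201490 to 0.08, AVESA.00010b.r2.6AG1056840 to 0.47, AVESA.00010b.r2.3DG0571360 to 0.12, AVESA.00010b.r2.7CG0683340 to 0.15 and AVESA.00010b.r2.5DG0955650 to 0.37. With median-of-ratios scaling AVESA.00010b.r2.6DG1153980 turned to -0.22, AVESA.00010b.r2.3CG0506070 to -0.20 and AVESA.00010b.r2.3DG0559390 to -0.35. AVESA.00010b.r2.3DG0559390 also turned to -0.13 with library weights and ranged from -0.15 to 0.15 without each library, below 0 without unshaded replicate 3 (-0.15) and without ear-shaded replicate 3 (-0.06). AVESA.00010b.r2.3CG0506070 ranged from -0.22 to 0.68, below 0 without unshaded replicate 2. AVESA.00010b.r2.3DG0559390 turned to -0.25 without both replicates 3, where AVESA.00010b.r2.6DG1153980 turned to -0.08.

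With the replicate block, 33446 genes were changed, 22128 higher and 11318 lower, and 23 lists passed. Deviations of same-numbered libraries from their group means correlated at -0.05, -0.05 and -0.15 over genes, no library correlated best with its own number, and the labels name no shared batch, so the samples share only a number. Depth is unknown, so its limit on low genes is not known either.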

Other observations

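The tests of scaling, surface tissue, shared reads, KEGG pathways and other splits, and the lists of late stages, were chosen after the result was seen.

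Cytosolic ribosomal protein genes fell as a group: 387 of 564 were lower and 28 higher, adjusted over the list alone 394 and 30, and their summed expression fell from 66800 ± 10700 to 35000 ± 7660 FPKM (camera, adjusted p = 2.26e-22; adjusted p = 0.696 with an estimated correlation). The S28e genes AVESA.00010b.r2.4DG0718680 and AVESA.00010b.r2.2CG0289250 fell 9.30-fold and 6.81-fold and the L38e gene AVESA.00010b.r2.2DG0351590 fell 2.04-fold, a call that ended without ear-shaded replicate 1 or 2, with quantile normalization and without the filter. AVESA.00010b.r2.3DG0559390 (S27Ae) was at 409 ± 89.3 and 417 ± 53.7 FPKM and AVESA.00010b.r2.5DG0955650 (S4e) at 455 ± 49.6 and 320 ± 62.9 FPKM, and neither passed. The S27Ae gene passed as higher with quantile normalization (1.12). The S4e gene passed as lower with median-of-ratios scaling (-0.91), with library weights (-0.70), with no mean trend and without ear-shaded replicate 3 (-0.68), and turned to 0.37 with quantile normalization. Plastid ribosomal protein genes went the other way, with 20 of 31 higher and 6 lower (camera, adjusted p = 0.0221). The cell wall list had 138 of 202 genes higher and 9 lower (camera, adjusted p = 2.28e-06), led by expansins, which loosen walls. AVESA.00010b.r2.1DG0177190, AVESA.00010b.r2.1AG0058750 and AVESA.00010b.r2.1CG0085030 rose 2.94-fold, 3.23-fold and 2.70-fold, and AVESA.00010b.r2.1DG0121100 and AVESA.00010b.r2.4AG0631280 rose 14.8-fold and 9.26-fold, the last 18.3-fold without unshaded replicate 2. The auxin list had 150 of 227 higher and 22 lower (camera, adjusted p = 0.000102), a list that also holds class III peroxidases. Lists of other hormones (120 higher and 33 lower of 214), phenylpropanoids (59 and 16 of 98), autophagy and proteolysis (64 and 5 of 114), light signalling (64 and 10 of 109), chlorophyll breakdown and senescence (15 and 1 of 21) and defence (86 and 11 of 174) also passed camera upward. The defence list's summed expression went the other way, from 7130 ± 1410 to 2030 ± 410 FPKM, and its 2 most abundant members, endochitinases, fell. Each of these calls was lost with an estimated correlation (adjusted p = 0.696).

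Several of these calls also ended under other settings. Without the filter those of plastid ribosomal proteins, other hormones, phenylpropanoids, light signalling and defence ended. Scaling each library to the same sum ended those of other hormones, phenylpropanoids and defence, as did AVESA loci alone. A mean of at least 5 FPKM and library weights each ended those of other hormones and defence. Without ear-shaded replicate 3 the calls of plastid ribosomal proteins (relative median 0.51), other hormones (0.32), phenylpropanoids (0.53) and defence (0.20) ended. Without unshaded replicate 3 those of plastid ribosomal proteins (0.46), other hormones (0.27) and defence (0.31) ended, as they did without both, and without unshaded replicate 1 that of defence (0.24). COG text alone ended those of plastid ribosomal proteins, other hormones, phenylpropanoids and defence, and KEGG text alone those of chlorophyll breakdown and defence. The calls of the cell wall, auxin and autophagy lists did not end in any setting but the estimated correlation. With median-of-ratios scaling 35 autophagy genes were higher and 19 lower, and 94 and 54 of the other hormones. The KEGG pathways of autophagy (other, yeast and animal) missed camera at the preset correlation (adjusted p = 0.0627, 0.104 and 0.167).

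The other 8 of the 12 lists that did not pass were fatty acid desaturation (3 higher and 5 lower of 9), glycolysis (76 and 54 of 208), clock (20 and 6 of 34), histones (101 and 30 of 328), heat shock (163 and 142 of 473), oxidative stress (153 and 69 of 359), abscisic acid (14 and 10 of 39) and nitrogen transport (67 and 28 of 146). With median-of-ratios scaling the balance turned for glycolysis (51 higher and 78 lower), histones (40 and 65), heat shock (85 and 189) and abscisic acid (11 and 14), and was near even for oxidative stress (115 and 113) and nitrogen transport (56 and 45). Heat shock then passed camera downward (relative median -0.15), as it did with library weights, without unshaded replicate 2 (-0.12) or 3 (-0.16), without ear-shaded replicate 3 (-0.17), without both replicates 3, and with AVESA loci, KEGG text or COG text alone. Histones passed upward with quantile normalization (relative median 0.23), fatty acid desaturation passed downward with COG text alone and the clock list upward with the patterns as first written. Adjusted over the list alone, 86 histone genes were higher and 22 lower, and in the rest of these 8 lists, and in those from plastid ribosomal proteins to defence, either count moved by at most 3. Single members still changed much. The catalases AVESA.00010b.r2.1AG0024260 and AVESA.00010b.r2.6CG1122490, which break down hydrogen peroxide, rose from 5.67 ± 4.44 to 236 ± 114 FPKM and from 5.64 ± 3.32 to 210 ± 82.7 FPKM, folds of 41.7 and 37.2. Without unshaded replicate 2 the folds were 76.1 and 55.8. The ascorbate peroxidases AVESA.00010b.r2.4CG1260560 and AVESA.00010b.r2.5DG0945730 rose 1.84-fold and 1.57-fold, calls that ended with median-of-ratios scaling, and a glutathione S-transferase (AVESA.00010b.r2.4AG0645890) 1.92-fold. The glutamine synthetases AVESA.00010b.r2.5AG0797710, AVESA.00010b.r2.1DG0134930 and AVESA.00010b.r2.6DG1173480 rose 4.20-fold, 4.43-fold and 4.67-fold and an amino acid transporter (AVESA.00010b.r2.UnG1410110) 4.96-fold. Over KEGG pathways, 40 of 279 passed camera, 27 upward and 13 downward, and 0 with an estimated correlation. Antenna proteins (41 of 42 higher), alpha-linolenic acid metabolism (62 of 90) and linoleic acid metabolism (23 of 27) were among those upward, and branched-chain amino acid biosynthesis (28 of 58 lower) among those downward.

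Photosynthesis genes were higher in grains from the darkened ears, and scaling between libraries is argued against, since the light-reaction median log2 fold change of 2.63 was 2.38 with median-of-ratios scaling, with an error of 0.07 from the libraries. Exchanged group labels, which would turn every direction given here, stay open: asparagine synthetase and phytochrome A, genes known as lowered by light, had medians 0.74 and 1.20 above that of all genes, as a test set beforehand required against an exchange. That bound was too weak for asparagine synthetase, whose genes went both ways (7 of 12 higher and 3 lower, with sums of 91.9 ± 7.07 and 93.7 ± 3.64 FPKM). The 4 phytochrome A genes went with the labels as given, 3 higher and 0 lower. Their sum was 2.71 ± 1.49 FPKM in unshaded and 10.7 ± 1.63 FPKM in ear-shaded grains, but these are few genes at low values. A larger share of green surface tissue may account for part of the rise and stays open, since the surface-layer list was higher (0.61), a call lost with an estimated correlation (adjusted p = 0.696), without the filter (0.03) and without unshaded replicate 2 (0.39). The KEGG pathway of cutin, suberine and wax biosynthesis did not pass (relative median 0.31, camera, adjusted p = 0.585). Lipid-transfer proteins of the surface-layer list did not move alike. The 3 most abundant did not pass while AVESA.00010b.r2.UnG1418490 rose 51.1-fold and AVESA.00010b.r2.7CG0683350 101-fold (165-fold without unshaded replicate 2). Unshaded replicate 3 had a surface-layer sum of 4490 FPKM, within the 4150 to 4730 FPKM of the ear-shaded libraries. Its light-reaction sum was 320 FPKM against at least 2650 FPKM. The surface-layer sum rests in large part on those 3 abundant genes, so it need not track surface tissue and cannot decide. A response of the grain to shading stays open too.

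Storage protein genes were lower in shaded grains. Reads divided among near-identical copies would leave the sum alike, and the sum was 3.69 times higher in unshaded grains, with the lowest unshaded library at 19000 and the highest shaded one at 9250 FPKM. For an earlier stage of grain development in shaded ears, which may be a candidate explanation, the values went both ways. The cell division list was higher (0.20) and the starch synthesis list lower, as a test set beforehand required. Both calls were lost with an estimated correlation (camera, adjusted p = 0.696), and the KEGG pathways of DNA replication and cell cycle did not pass. The chlorophyll breakdown and senescence list was higher too (0.84, camera adjusted p = 0.00903, and 0.696 with an estimated correlation), a call that also ended with KEGG text alone. Chlorophyll synthesis genes were higher as well (0.87), so that list cannot tell a late stage from greener grains. The embryo and late maturation list lay at 0.66, with 652 ± 186 and 1450 ± 139 FPKM in sum, and missed the threshold in the comparison as fitted. The labels give no grain age at harvest, so an earlier stage and a direct effect of shading on storage genes both stay open.

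Replicate 3 of each group lay toward the other group. Mixing of grains or RNA would give 1 share of the other group's profile from both sets of genes. In unshaded replicate 3 that share was 1.15% from the 1085 genes high in shaded and 19.5% from the 586 genes high in unshaded libraries. In ear-shaded replicate 3 it was 35.9% and 1.83%, and the larger ratio of the estimates was 19.6. The genes were chosen in replicates 1 and 2 alone, as at least 10 times higher and at 5 FPKM or more. That choice can itself raise the 19.5% and 35.9%, so the ratio cannot decide. The lower estimates, 1.15% and 1.83%, argue against simple mixing in larger shares. No biological explanation was tested.

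Of the 10 splits of the 6 libraries into 3 and 3, only 1, the real one, gave as many called genes with limma, for the changed, higher and lower genes alike. The real split gave 37227, 24724 and 12503 genes and the highest other split 0, with 1626 genes at an unadjusted p under 0.05 against 39426. With 10 splits no share under 0.05 can be had.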
